A study of Homo sapiens with 24 samples.

How the data were processed

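Total RNA from primary human coronary artery endothelial cells was end-labelled and hybridised to Agilent human miRNA arrays, per the labels. The deposited files are the scanner output of 24 arrays and a value table of the submitters. Each scanner file gives intensity values per spot, made with Agilent Feature Extraction 9.5.3.1 per the file headers, and its processed signal is a background-subtracted intensity of 1 array with no scaling between arrays. The deposited value table holds a signal per probe on a linear scale, close to the scanner signal times 1 factor per array (0.200 to 0.836), with small values set to a floor for each array. Of the detected probes, 94.6% to 100% of an array lay within 20% of that product, but 68.8% on MF control 6 h replicate 1 and 86.1% on SD control 24 h replicate 1, the arrays with bright patches. What set that factor is not stated, and the columns are neither log values nor centred. All 2689 entries in it matched a probe. The column medians of the deposited table, in replicate order, were 0.00268, 0.00256 and 0.00249 for SD control 6 h, 0.216, 0.148 and 0.0999 for SD 10 Gy 6 h, 0.00286, 0.00297 and 0.00268 for SD control 24 h, and 0.188, 0.00419 and 0.00255 for SD 10 Gy 24 h. They were 0.00263, 0.0797 and 0.273 for MF control 6 h, 0.0415, 0.110 and 0.00901 for MF 2 Gy x 5 6 h, 0.205, 0.0772 and 0.00358 for MF control 24 h, and 0.00209, 0.00304 and 0.00335 for MF 2 Gy x 5 24 h. In columns whose median equals the lowest value most probes lay at the floor, so the comparisons use the scanner intensity and the deposited values serve as an alternative.

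Of 15739 spots on the array, 15024 were not controls. Spots flagged as non-uniform or as population outliers were removed, 5.18% to 13.7% of an array, and no spot was saturated. The processed signal was averaged over the spots of a probe, divided by the 75th percentile of the array over the 165 probes detected on all arrays, and multiplied by the mean of those percentiles, which ran from 248.5 to 1253. The probes of a miRNA were summed, a floor of 1 was set and log2 was taken. A probe counted as detected where over 0.5 of its spots were well above background, and a miRNA was tested where it was detected on all 3 arrays of at least 1 group. Of 851 human miRNAs 200 were tested, 101 were detected on all arrays and 619 on none. Probes for viral miRNAs were not used here. The number of arrays limits the precision, with a median SE of 0.19 on the log2 scale. A fold for a miRNA detected on no array of 1 group is a lower bound, computed by setting each array of that group to its measured signal or the lowest signal detected on that array, whichever is higher, and no fold is given where both groups were below background. The names are those of the array, and 185 of 200 matched a miRNA gene in a RefSeq table (assembly GRCh38.p14), 163 to 1 gene and 22 to several, while 15 did not match. No coordinates were used except to find neighbouring genes within 10000 bases.

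Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 group means over all 24 arrays, Benjamini-Hochberg adjustment and a threshold of 0.05. There were 11 contrasts: 4 of irradiated against control arrays, their average, differences of schedules and of times, and controls between schedules. Lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, for lists with at least 3 tested members. fry tests whether the members of a list move on balance in 1 direction, not whether they differ from other miRNAs. For the p53-responsive list, which camera did not call, its adjusted p was 4.1e-05 in SD at 24 h and 1.4e-05 in MF at 6 h. The lists were p53-responsive, miR-17-92, miR-106b-25 and miR-106a-363, let-7, miR-15/16, endothelial-enriched, inflammation and NF-kB, senescence-associated in endothelium, miR-29, miR-23/24/27, miR-181, the imprinted 14q32 cluster, C19MC on chromosome 19, markers of smooth muscle, fibroblast and muscle, of epithelium and of blood cells, GC-rich array miRNAs, and fragments of other RNAs. Several lists share members. The overlap of calls between comparisons was tested with Fisher's exact test. Named miRNAs were, in each comparison with a control, the 10 largest rises and falls among calls whose arrays did not overlap, or the 5 smallest p-values where fewer than 5 passed, up to 4 members of each list with the smallest p, and always miR-34a, miR-126, miR-21, miR-146a, miR-155 and miR-210. For the average they were the 10 largest rises and falls, and for the other contrasts the 5 largest each way or the 3 smallest p-values. The groups, contrasts, lists, rule for named miRNAs and most other settings tried were fixed before the data were examined.

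On simulated data for 200 miRNAs, with the means and spreads of these arrays, independent noise and known changes, a 2-fold change was found in 72% of cases in SD at 6 h, 77.5% in SD at 24 h, 74% in MF at 6 h and 76.5% in MF at 24 h. In the same comparisons 4.55%, 2.39%, 3.44% and 5.84% of the simulated calls were false. The simulated arrays carried no differences in brightness and were not scaled, so these shares leave out errors of array scaling. A 1.5-fold change was found in 45.5% to 51.5%. For schedule differences a 2-fold change was found in 61% at 6 h and 54% at 24 h. A list raised 2-fold in SD at 24 h was found by camera with its preset correlation in 70 of 70 runs. In 800 tests of lists without shared members, 0 were falsely called higher, while false calls of lower lists were not counted. Since the simulated noise was independent between miRNAs, these runs do not show how camera behaves where members of a list vary together.

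Arrays lay on 3 slides. The first held SD replicates 1 and 4, the second SD replicate 3 and MF replicate 1, and the third MF replicates 2 and 3. Each slide held the irradiated and control arrays of a replicate, so slide could be fitted as a block. The place of an array on the slide followed its group in every column of arrays, so place and group cannot be told apart. Slides differed in scan date as a whole, so no separate block for the date was run. Whether replicate numbers pair arrays was checked by correlating each array's deviation from its group mean with that of the array of the same number. The correlations were 0.25, 0.23 and 0.66 in SD at 6 h, 0.40, 0.67 and 0.55 in SD at 24 h, 0.69, 0.084 and 0.047 in MF at 6 h, and 0.83, 0.85 and 0.34 in MF at 24 h. By the criterion of over 0.1 the numbers therefore match arrays in 3 of the 4 comparisons, and a replicate block was run as an alternative. For SD at 6 h replicate 1 and MF at 6 h replicate 3 another number correlated more, with 0.33 and 0.34. For every other replicate its own number was highest. Each number also filled 1 column of a slide, so these correlations cannot tell paired samples from place. No pair of arrays was identical, and the smallest median difference in a group was 0.0853 on the log2 scale.

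Other settings fixed beforehand were the 75th percentile over all human probes, quantile normalization, the median over detected probes, normexp background correction with an offset of 50, no filter, a filter for miRNAs detected on all arrays, the brightest probe alone, the total gene signal of Feature Extraction, a floor of 8, the authors' value table, a fit on the compared groups alone, a replicate block, a slide block, eBayes with trend and robust, array weights, and leaving out each array. Chosen after seeing the data were the median over spots, arrays centred on the median of tested miRNAs, scaling without fragments and GC-rich miRNAs, leaving out 2 control arrays with bright background patches, and leaving out the 2 control arrays with the fewest detected miRNAs. The packages data.table (version 1.17.8), jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9 were also used.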

Results

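MicroRNA levels were measured with single-colour Agilent arrays in primary human coronary artery endothelial cells, the cells that line the arteries of the heart, after X-irradiation. The cells received a single dose of 10 Gy (SD) or 5 fractions of 2 Gy (MF), given at an interval of 6 h on each day, and were harvested 6 h or 24 h after the dose or the last fraction. Each schedule and time had its own unirradiated controls, which gave 8 groups of 3 arrays, 24 arrays in all. Of 851 human miRNAs on the array, 122 to 214 were detected on each array, and 200 were tested. The number of arrays limits the precision. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between samples, which can be technical. The 5 brightest signals came from miR-720, with 26.7% of the human signal, miR-923 with 13.8%, miR-21 with 12.6%, miR-1274b with 6.00% and the endothelial miR-126 with 4.52%. Changes are given as log2 fold changes ± SE, between the means of 3 irradiated and 3 control arrays. The SE and p-values come from the limma fit over all 24 arrays, with the spread of a miRNA pooled over the 8 groups. Because the median change of all tested miRNAs depended on the array scaling, changes relative to that median are given as well. The median was 0.06 in SD at 6 h, 0.39 in SD at 24 h, 0.34 in MF at 6 h and 0.18 in MF at 24 h.

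The comparison of fractionated irradiation with its control at 24 h asked which miRNAs had changed a day after the fractionated course, which the labels describe as a model of conventional fractionation. The growth-promoting miR-17-92 cluster was lower: 7 of its 8 tested members fell, among them miR-20a with −0.88 ± 0.10 (0.543-fold), miR-17 with −0.89 ± 0.13 and miR-19b with −0.64 ± 0.08. miR-34a, a direct target of p53 that restrains the cell cycle, rose 2.07-fold (1.05 ± 0.14), and miR-34b* of the same family rose by 1.25. miR-146a, which dampens NF-kB signalling, rose 2.27-fold (1.18 ± 0.18), miR-181a rose 1.99-fold (0.99 ± 0.12), and miR-21 rose by 0.58 ± 0.10. miR-7 had the largest fall, −1.25 ± 0.19. Relative to the median of tested miRNAs these changes were −1.06 for miR-20a, 0.87 for miR-34a, 1.00 for miR-146a, 0.81 for miR-181a and −1.43 for miR-7.

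Of the 5 tested p53-responsive miRNAs, 2 rose, and 3 rose adjusted over the list alone. Of 5 members of the miR-23/24/27 clusters, which are active in vessel growth, 4 rose, with miR-23b at 0.81 and miR-23a at 0.70, and 5 rose adjusted over the list alone. Of 11 senescence-associated miRNAs 5 rose, and 8 rose adjusted over the list alone. Of 16 endothelial-enriched miRNAs 6 rose by either adjustment, including miR-31 with 0.66 ± 0.12 and miR-222 with 0.63, while miR-126, which maintains vessel integrity, was at 0.16 (adjusted p 0.49). Of 5 inflammation miRNAs 3 rose by either adjustment, and miR-155, a promoter of inflammatory signalling, fell by 0.38. The miR-15/16 family, which represses cyclins, moved apart: miR-15a, miR-15b and miR-16 fell, by 0.48, 0.65 and 0.52, and miR-424 rose by 0.64. In the clusters related to miR-17-92, miR-106b-25 and miR-106a-363, 2 of 5 members fell (miR-18b −0.95 and miR-20b −0.88), and 4 fell adjusted over the list alone. Of 35 tested members of the imprinted 14q32 cluster 7 rose by either adjustment, among them miR-127-3p with 0.89 and miR-136 with 0.73. Of the miR-29 family, which represses matrix genes, 1 of 4 rose (3 adjusted over the list alone), of the miR-181 family 1 of 3 by either adjustment, and of the 9 members of the let-7 family none was called. The hypoxia-induced miR-210 was at −0.04 (adjusted p 0.95). GC-rich miRNAs and fragments of other RNAs, both read as signs of array background or RNA quality, had 1 of 17 and 2 of 9 members that fell, including miR-1275 with −0.94 and miR-886-3p with −0.93 ± 0.26.

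In the limma test 49 miRNAs passed at 24 h after the last fraction, 31 that rose and 18 that fell. Adjusted p was 1.37e-05 for miR-20a, miR-19b and miR-181a, 2.09e-05 for miR-34a and 9.62e-05 for miR-146a and miR-7. In each named call the 3 irradiated arrays lay on one side of the 3 control arrays, a placement that chance gives to 10% of unselected miRNAs. The rule for naming the largest rises and falls required it, so for those miRNAs it is no separate support. Against the other miRNAs, camera with its preset correlation called the miR-17-92 cluster lower (adjusted p 2.25e-10), and that call held with an estimated correlation (adjusted p = 0.0134). The camera calls for the senescence list (0.00202), the miR-106b-25 and miR-106a-363 clusters (0.00202), the miR-23/24/27 clusters (0.00687) and the endothelial list (0.037) were lost with an estimated correlation, where adjusted p = 0.24, 0.24, 0.25 and 0.48. With a replicate block 70 miRNAs passed and the fragment list was also called lower (adjusted p 0.034, against 0.058 without it), and with a slide block 63 miRNAs passed. On the 2 slides taken singly miR-34a was at 0.90 and 1.13, miR-20a at −0.89 and −0.88, and miR-146a at 1.31 and 1.12. These values come from the arrays that gave the calls and are no separate support. With arrays centred on the median of tested miRNAs, 17 rose and 20 fell. With the 75th percentile over all human probes, 1 miRNA rose and none fell, the miR-106b-25 and miR-106a-363 median turned to 0.18, and miR-15a, miR-16 and miR-155 turned to 0.04, 0.0011 and 0.14. The miR-17-92 median stayed negative under every scaling tried.

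**Figure D1:**
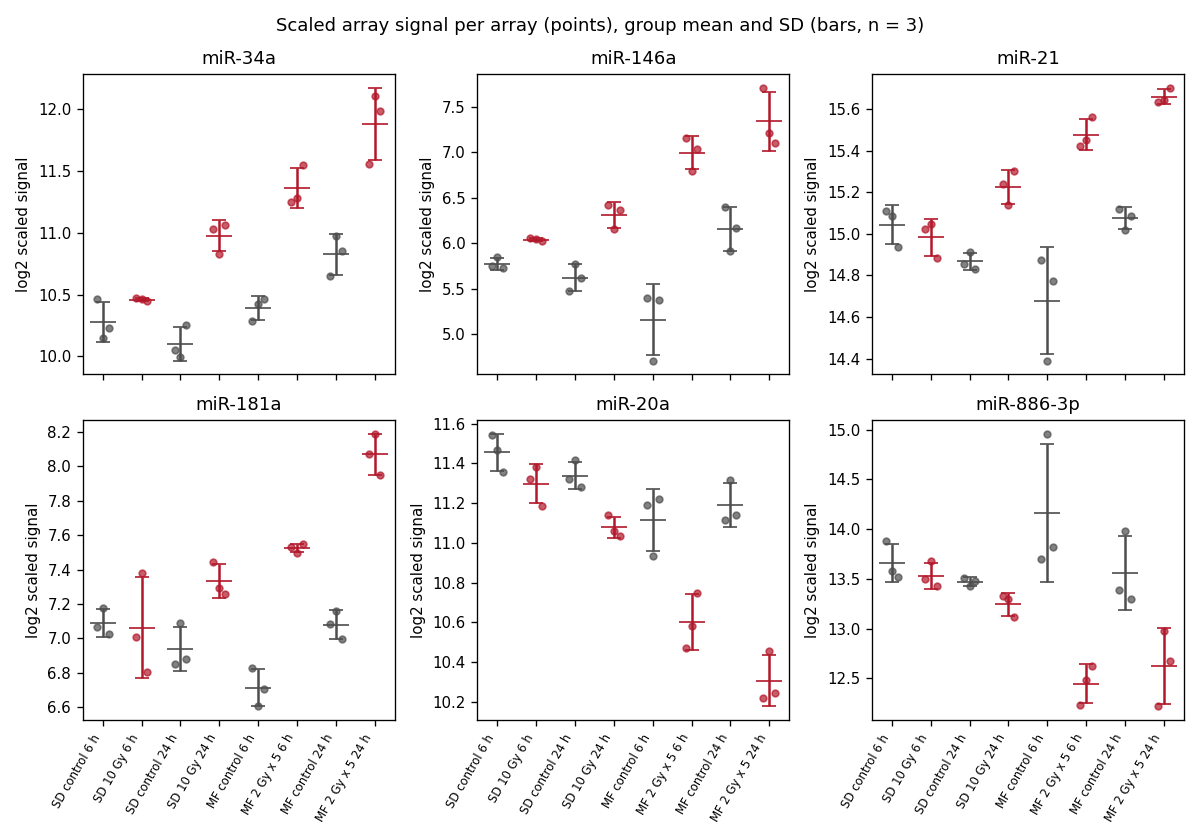
Log2 scaled signal (vertical axis) of 6 miRNAs on each of the 24 arrays, with points for arrays, bars for mean ± SD of 3 arrays, grey for controls and red for irradiated arrays. In MF at 24 h miR-34a, miR-146a, miR-21 and miR-181a were higher and miR-20a and miR-886-3p lower than in their controls, with log2 fold changes of 1.05, 1.18, 0.58, 0.99, −0.88 and −0.93, and these directions held under each of 7 other array scalings.

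At 6 h after the last fraction, the comparison with the matched control asked for the early response to the fractionated course. miR-146a, which was detected on 2 of 3 control arrays, rose 3.56-fold (1.83 ± 0.18). miR-34a rose 1.96-fold (0.97 ± 0.14), miR-21 rose 1.74-fold (0.80 ± 0.10) and miR-181a rose by 0.81 ± 0.12. Of the 14q32 cluster 23 of 35 members rose by either adjustment, with miR-410 at 1.16 ± 0.20, miR-377 at 1.03 and miR-376c at 0.73. As a list it was called against other miRNAs by camera, but not with an estimated correlation (adjusted p = 0.335), and 9 of the 35 were detected in 1 of the 2 groups alone. miR-409-5p of that cluster, not detected in the control, was at least 2.18-fold higher, and miR-136* at least 1.59-fold higher. The largest fall was that of miR-886-3p, a fragment of a vault RNA, with −1.71 ± 0.26, and the growth-related miR-7 fell by 0.94. Relative to the median these changes were 1.49 for miR-146a, 0.63 for miR-34a, 0.46 for miR-21, 0.81 for miR-410 and −2.05 for miR-886-3p.

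Of the p53-responsive list 3 of 5 rose by either adjustment, with miR-34b* at least 1.60-fold higher. All 5 members of the miR-23/24/27 clusters rose by either adjustment (miR-27a 0.66, miR-23a 0.69, miR-27b 0.73), and so did 9 of 11 senescence-associated miRNAs, among them miR-22 with 0.84 and miR-146a. Of the endothelial list 9 of 16 rose, 10 adjusted over the list alone, with miR-10b at 1.05 and miR-126 at 0.32 (adjusted p 0.0695). Of the inflammation list 2 of 5 rose, 3 adjusted over the list alone, and miR-155 was at −0.05 (adjusted p 0.77). Of the let-7 family, which is high in differentiated cells, 5 of 9 rose by either adjustment, such as let-7f with 0.63 and let-7e with 0.63. In the miR-15/16 family miR-195, miR-497, miR-503 and miR-424 rose by 0.56 to 0.69 and miR-15b fell by 0.27. The miR-29 family had 2 of 4 members that rose (3 adjusted over the list alone) and the miR-181 family 2 of 3 by either adjustment. The miR-17-92 cluster had 7 of 8 members that fell by either adjustment (miR-17 −0.63 ± 0.13, miR-20a −0.51 ± 0.10), and miR-18b was the sole member of 5 in the related clusters that fell (−0.57). miR-210 was at 0.36 (adjusted p 0.28). Of the fragments 7 of 9 fell by either adjustment, with miR-1274a at −1.04 and miR-1280 at −1.05, and of the GC-rich miRNAs 6 of 17 fell by either adjustment, with miR-1275 at −1.11. miR-1288, not detected after irradiation, was at least 2.78-fold lower.

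In the limma test 105 miRNAs passed in this comparison, 78 that rose and 27 that fell. The control arrays were dimmer as a group, with 75th percentiles of 248.5 to 578.9 against 549.2 to 1058 after irradiation. They also had fewer detected miRNAs, 123 to 168 against 191 to 211, so array brightness and irradiation cannot be told apart in these calls. Adjusted p was 1.26e-06 for miR-146a, 8.77e-05 for miR-34a, 4.49e-05 for miR-21 and 0.000365 for miR-410. In each named call but miR-10b and miR-1228 the 3 irradiated arrays lay on one side of the 3 controls, which the rule for naming the largest rises and falls required. The camera calls were lost with an estimated correlation: for the miR-17-92 cluster adjusted p went from 2.62e-06 to 0.127, for the 14q32 cluster from 0.000813 to the 0.335 above, for the fragments from 2.62e-06 to 0.212, for the senescence list from 0.0093 to 0.335, for the miR-23/24/27 clusters from 0.0114 to 0.335 and for the GC-rich list from 0.0054 to 0.37. With members not detected in 1 group set at their bound, the 14q32 median went from 0.77 to 0.59. With a replicate block 120 miRNAs passed and with a slide block 116, and both blocks called the endothelial list higher (adjusted p 0.028 and 0.038, against 0.063 without a block). On the single slides miR-146a was at 1.76 and 1.87 and miR-886-3p at −1.46 and −1.84. Centred arrays gave 33 that rose and 36 that fell, and the 75th percentile over all human probes 22 and 0. Normexp background correction gave 17 that rose and 112 that fell. Under it the medians of 14q32 (−0.54), the miR-15/16 family (−0.24), the miR-181 family (−0.30) and the senescence list (−0.02) turned negative, and so did miR-146a (−0.05), miR-410 (−0.08) and miR-181a (−0.10). The inflammation median turned to −0.05 with normexp. The medians of miR-17-92, the fragments, p53, miR-23/24/27, endothelial miRNAs and let-7 kept their sign under every scaling tried.

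The single dose was set against its control at 24 h to ask for the later response to a large, hypofractionated dose. miR-34a rose 1.83-fold (0.87 ± 0.14), as did members of the 14q32 cluster, with miR-136 at 0.91 ± 0.13, miR-654-3p at 0.80, miR-409-3p at 0.77 and miR-127-3p at 0.76. miR-146a rose by 0.69 ± 0.18, miR-503 by 0.77 ± 0.17 and miR-21 by 0.36 ± 0.10. miR-7 was the sole miRNA that fell (−0.61 ± 0.19). Relative to the median of tested miRNAs miR-34a was at 0.48, miR-136 at 0.52, miR-146a at 0.30, miR-21 at −0.03 and miR-7 at −1.003.

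Of the 14q32 list 22 of 35 rose and 28 rose adjusted over the list alone, with miR-134, not detected in the control, at least 2.08-fold higher. Of the p53-responsive list 3 of 5 rose by either adjustment, miR-34a, miR-34a* and miR-34b*. Of the inflammation list 4 of 5 rose by either adjustment, and miR-155 was at −0.17 (adjusted p 0.29). The endothelial list had 6 of 16 members that rose, 7 adjusted over the list alone, with miR-222 at 0.55, miR-27a at 0.36 and miR-126 at 0.10 (adjusted p 0.57). The senescence list had 5 of 11 (8 adjusted over the list alone), the miR-29 family 2 of 4 (3), the miR-23/24/27 clusters 2 of 5 (4), the miR-181 family 1 of 3 (2) and the miR-15/16 family 1 of 7 (1), the numbers in parentheses again being those adjusted over the list alone. No member of the miR-17-92 cluster was called by either adjustment, with miR-20a at −0.26 (adjusted p 0.061) and miR-19b at −0.21 (0.057), and none of the related clusters, let-7 or the fragments was called. miR-210 was at 0.69 (adjusted p 0.059). Of the GC-rich miRNAs 8 of 17 rose by either adjustment, with miR-1915 at 1.22, but 5 of the 8 were detected in both groups and miR-1181 was below background on all 6 arrays. With that limit, this array-related list moved in the same comparison as the groups above.

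In the limma test 62 miRNAs passed, 61 that rose and 1 that fell, with adjusted p of 0.000518 for miR-34a, 0.000216 for miR-136, 0.0103 for miR-146a and 0.0247 for miR-7. In each named call the 3 irradiated arrays lay on one side of the 3 controls, which the rule for naming the largest rises and falls required. As a group against the others, the miR-17-92 cluster was lower by camera (median −0.21 against 0.40, adjusted p 1.16e-09) and remained so with an estimated correlation (adjusted p = 0.0188). The 14q32 call (adjusted p 6.12e-06) and the lower calls for the miR-106b-25 and miR-106a-363 clusters (0.0066) and let-7 (0.013) were lost with an estimated correlation, where adjusted p = 0.31, 0.35 and 0.44. A replicate block gave 87 miRNAs and a slide block 75, and on the single slides miR-34a was at 0.89 and 0.83 and miR-146a at 0.84 and 0.38. The count fell to 20 without SD control 24 h replicate 1 and to 28 without SD 10 Gy 24 h replicate 1. The upward calls also depended on the scaling. Centred arrays gave 1 that rose and 14 that fell. The 75th percentile over all human probes gave none, and turned the 14q32 median to −0.27, the p53 median to −0.05 and every other list median negative. With centred arrays the medians of 14q32 (0.22) and p53 (0.44) stayed positive. Those of the endothelial, inflammation, let-7, miR-15/16, miR-181, miR-23/24/27, miR-29, senescence and fragment lists turned negative, among them inflammation with −0.004 and let-7 with −0.36. The median of the miR-106b-25 and miR-106a-363 clusters, 0.000465 under the main scaling, turned negative as well. The miR-17-92 median was negative under every scaling.

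At 6 h after the single dose, the comparison that asked for the early response to the large dose gave few differences. miR-34a was at 0.18 ± 0.14, miR-146a at 0.27 ± 0.18, miR-21 at −0.06, miR-126 at −0.09, miR-155 at −0.02 and miR-210 at 0.23, all with an adjusted p of 0.99. By limma 1 miRNA passed, the GC-rich miR-1181 with an adjusted p of 0.043, which was below background on all 6 arrays, so no fold is given for it. With a replicate block or a slide block 0 miRNAs passed in limma, and 15 had an unadjusted p under 0.05 without a block. The next smallest p-values belonged to miR-369-5p (adjusted p 0.081), detected on 1 of the 6 arrays so that no fold is given, miR-150* at least 1.59-fold higher (0.47), miR-572, below background in both groups (0.47), and miR-136* with 0.59 (0.59). Besides miR-1181 no list had a called member, and adjusted over the list alone 1 member of 14q32 and 1 GC-rich miRNA rose. Camera called 14q32 (adjusted p 0.000469) and the GC-rich list (0.000472) higher and miR-17-92 lower (0.013), with medians of 0.18, 0.41 and −0.11. With members not detected in 1 group at their bound the first 2 medians were 0.14 and 0.23. With an estimated correlation each had adjusted p = 0.50, and the mean of miR-17-92 was 0.10, opposite in sign to its median.

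**Figure D2:**
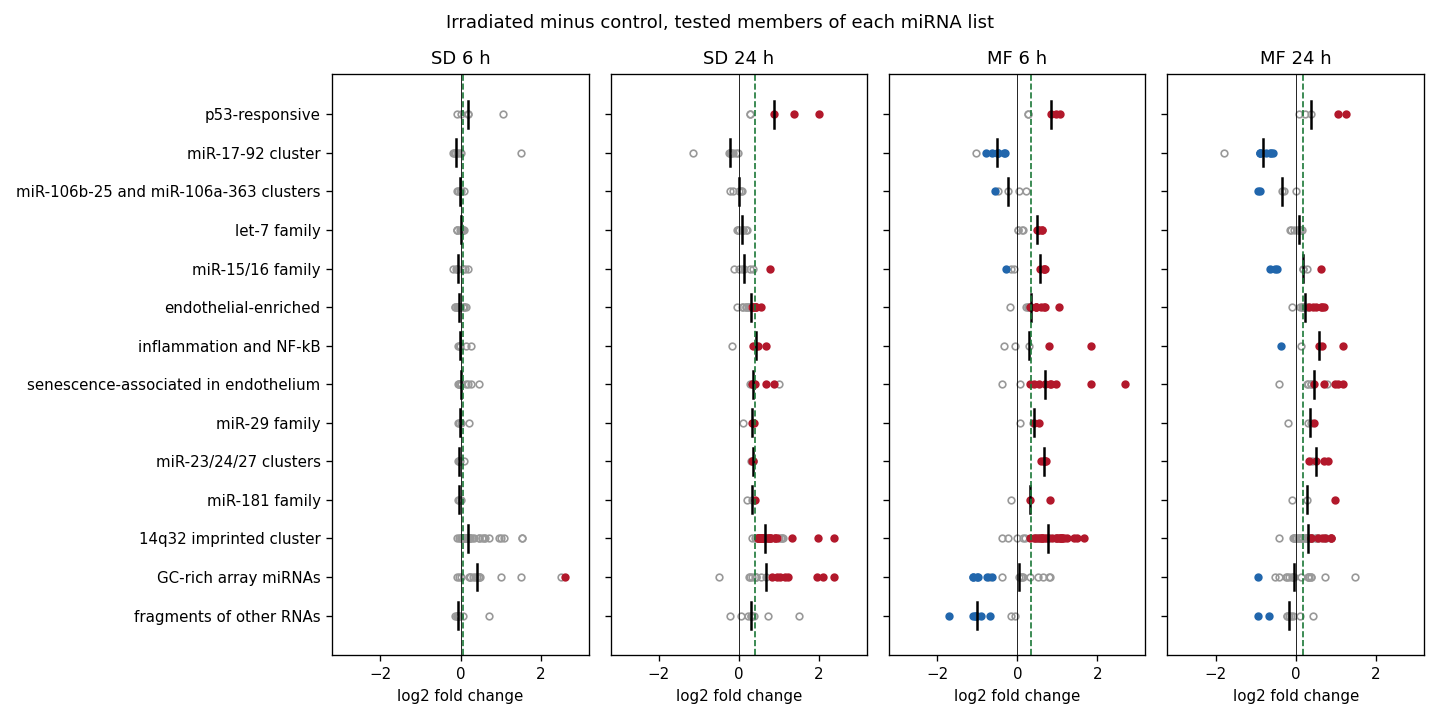
Log2 fold change (horizontal axis) of each tested member of 14 miRNA lists in the 4 comparisons of irradiated with control arrays. Red points rose, blue points fell and open grey points were not called, black ticks are list medians and the green dashed line is the median of all tested miRNAs, with the miR-17-92 median at −0.50 and −0.81 in MF at 6 h and 24 h under the main scaling and negative under every other, and the 14q32 median at 0.65 in SD at 24 h but −0.27 when scaled over all human probes, and at 0.77 in MF at 6 h but −0.54 with normexp.

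Averaged over the 4 comparisons, miR-146a (0.99 ± 0.09) and miR-34a (0.77 ± 0.07) rose with an adjusted p of 1.83e-07 each. miR-20a fell by 0.45 ± 0.05 and miR-7 by 0.73, while miR-155 fell by 0.15. All 5 p53-responsive miRNAs, all 5 of miR-23/24/27, 10 of 11 of the senescence list, 10 of 16 endothelial miRNAs and 30 of 35 of 14q32 rose, with 5, 5, 10, 10 and 31 adjusted over the list alone, and 7 of 8 of miR-17-92 fell (7). GC-rich miRNAs were called both ways, such as miR-150* (0.96), miR-1915 (0.74) and miR-1275 (−0.64). Of the fragments, miR-886-3p (−0.75) and miR-1274a (−0.24) were among those that fell. miR-15a, miR-15b and miR-16 fell and the other 4 members of their family rose. In all 126 miRNAs passed in limma, 106 that rose and 20 that fell. Counts were 137 with a replicate block and 134 with a slide block, and centred arrays 42 that rose and 37 that fell. Camera called miR-17-92 lower (adjusted p 1.26e-10, 0.0119 with an estimated correlation). It called 14q32 (0.000131) and the senescence list (0.0145) higher, but with an estimated correlation adjusted p = 0.27 for both. Under normexp the 14q32 median of this average turned to −0.09.

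Calls were shared among 3 of the 4 comparisons. miR-34a, miR-34b*, miR-146a, miR-21, miR-181a, miR-222, miR-24, miR-27a, miR-29a and miR-136 were among 20 that rose in SD at 24 h and in MF at both times, and miR-7 fell in all 3. In MF 28 rose and 13 fell at both times, the latter including miR-17, miR-18a, miR-19a, miR-19b, miR-20a, miR-92a and miR-15b. The rises of SD at 24 h and MF at 24 h shared 22 miRNAs where 9.46 would be shared if miRNAs were independent (Fisher's exact test, adjusted p 1.82e-06). But miRNAs can vary together, and both comparisons use the same pooled spread of each miRNA, so that p-value can overstate the overlap. That overlap depended on the scaling, with 41 shared rises for the total gene signal, 0 to 4 for 5 other scalings and 1 for normexp. Under the main scaling no miRNA rose in one comparison and fell in another. Quantile normalization gave 1 such miRNA, between MF at 6 h and 24 h, and the total gene signal 1, between SD at 24 h and MF at 6 h. Over the 101 miRNAs detected on all arrays the effects of MF at 6 h and 24 h correlated with r 0.75 (Spearman 0.77), and those of SD and MF at 24 h with r 0.74 (Spearman 0.67). The other pairs correlated less, with r 0.39 for SD at 24 h and MF at 6 h, 0.39 for SD at 6 h and 24 h, 0.21 for SD and MF at 6 h, and 0.15 for SD at 6 h and MF at 24 h (Spearman 0.36, 0.35, 0.36 and 0.21). These correlations run across miRNAs, which are not independent replicates.

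**Figure D3:**
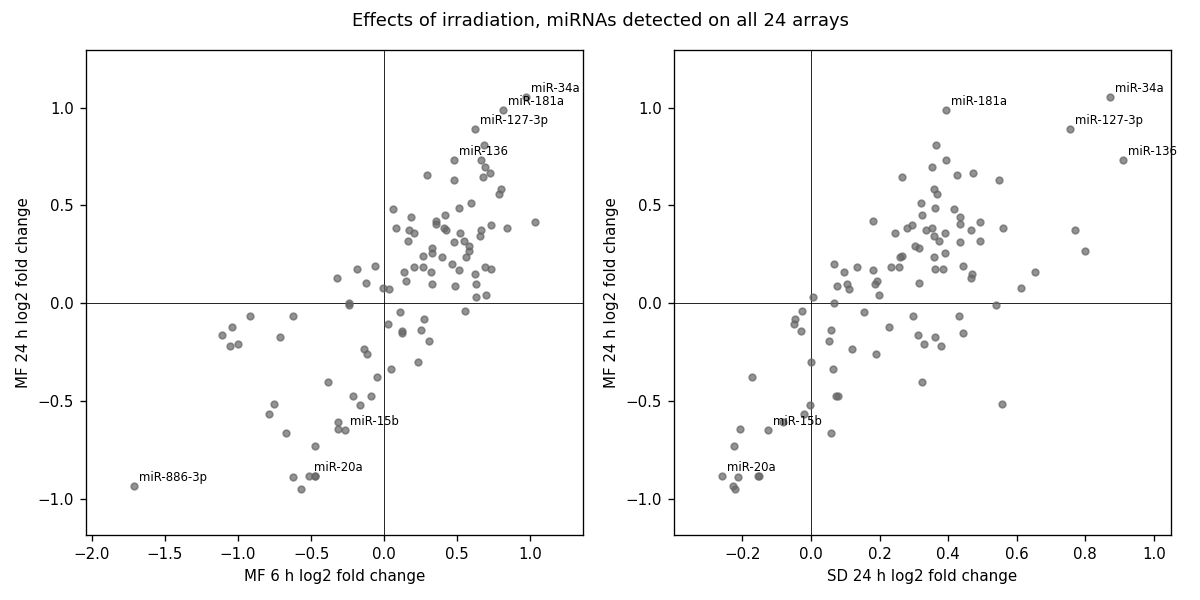
Log2 fold changes of 101 miRNAs detected on all arrays, MF at 6 h against MF at 24 h and SD at 24 h against MF at 24 h, with each point a miRNA. The effects lie along a common line (r 0.75 and 0.74), with miR-20a low and miR-34a high on the MF axes. The height of the whole cloud depends on the array scaling, and miR-34a in SD at 24 h turned to −0.05 when scaled over all human probes.

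Whether the schedules differed was tested as the difference of their effects, SD minus MF. At 6 h miR-146a rose less after the single dose, with a difference of −1.57 ± 0.25 (adjusted p 0.00157), and so did miR-410 (−1.01), miR-377 (−0.97), miR-337-5p (−0.96) and miR-379 (−0.86). Under 7 other scalings miR-146a was called in 6 and miR-377 in 2, while miR-410, miR-337-5p and miR-379 were called in 0. With normexp, which is not among those 7, the miR-146a difference was not called. miR-886-3p (1.58 ± 0.37), miR-923 (1.20), miR-1274a (1.00), miR-7 (0.82) and miR-18b (0.65) were higher in SD relative to MF. All 5 members of miR-23/24/27, 7 of 11 of the senescence list, 9 of 35 of 14q32, 3 of 16 endothelial and 2 of 5 p53-responsive miRNAs were lower, with 5, 8, 11, 4 and 2 adjusted over the list alone. In limma 34 miRNAs passed, 6 with a positive and 28 with a negative difference, against a median difference of −0.24, and 8 of the 34 were called in at least 5 of the 7 other scalings. Centred arrays gave 16 and 4, and the scaling over all human probes gave 0. Counts with a replicate block and a slide block were 73 and 53. Within the slide that held both schedules, with 1 array a group, miR-146a differed by −1.57. The count was 13 without SD control 6 h replicate 3, 22 without its replicate 1, and 13 without MF control 6 h replicate 2. It was 14, 15 and 17 without MF 2 Gy x 5 6 h replicate 1, 2 and 3, and 19, 20 and 15 without SD 10 Gy 6 h replicate 1, 3 and 4. Camera called 7 lists, with GC-rich miRNAs and fragments (both adjusted p 1.1e-05) and miR-17-92 (0.000165) as higher in SD, and the senescence, miR-23/24/27 (both 0.0025), endothelial (0.010) and 14q32 (0.029) lists as lower. None held with an estimated correlation, where adjusted p = 0.17 for the first 3 and 0.17, 0.19, 0.43 and 0.47 for the others, and with a replicate block the 14q32 call was lost (0.077).

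At 24 h no schedule difference passed in limma, with 32 miRNAs at an unadjusted p under 0.05. miR-20a (0.62), miR-130b (0.55) and miR-19b (0.44) came closest, each with an adjusted p of 0.051. Adjusted over the list alone, 7 of 8 members of miR-17-92 were higher in SD, that is less reduced, and camera called that list (adjusted p 7.7e-05, 0.13 with an estimated correlation). Camera also called the senescence (0.00031), miR-23/24/27 (0.0013) and endothelial (0.0014) lists lower in SD, with adjusted p = 0.13, 0.21 and 0.30 with an estimated correlation. A replicate block gave 18 miRNAs and a slide block 13, and with these blocks the miR-106b-25 and miR-106a-363 clusters were called higher (0.020 and 0.021, against 0.067) and the inflammation list lower (0.047 and 0.048, against 0.051), and with the replicate block the GC-rich list higher (0.047, against 0.067). Between times, the effect of SD on miR-136 was larger at 24 h than at 6 h by 0.88 ± 0.18 (adjusted p 0.023), the sole call of 200, with 28 at an unadjusted p under 0.05. It was called in 0 of 7 other scalings (0.02 to 0.83), and the count fell to 0 without each of 9 of the 12 SD arrays. On the slides it was larger by 1.01 and 0.62. A replicate block gave 9 and a slide block 2. Camera called miR-17-92 lower at 24 h (0.0002, 0.32 with an estimated correlation), and the miR-106b-25 and miR-106a-363 clusters with either block (0.046 and 0.045, against 0.060). In MF no miRNA passed between times in limma, with 34 at an unadjusted p under 0.05 and 1 with a replicate block. miR-410 (−1.07), miR-106b (−0.53) and miR-487b (−0.47) had the smallest p, each with an adjusted p of 0.21. Camera called fragments (3.4e-05) and GC-rich miRNAs (0.013) higher and the miR-15/16 and 14q32 lists (both 0.034) lower at 24 h than at 6 h, with adjusted p = 0.61, 0.73, 0.73 and 0.73 with an estimated correlation. The 14q32 call was lost with a replicate block (0.107) and a slide block (0.063).

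The unirradiated controls of the schedules differed as well, and the labels give them different seeding densities, with fewer cells seeded for MF than for SD. GC-rich miRNAs were higher in the MF controls: 13 of 17 at 6 h and 10 of 17 at 24 h, with 16 and 10 adjusted over the list alone. Of these, miR-1181 and miR-572 at 6 h and miR-134 at 24 h were below background in both groups. miR-150*, not detected in the SD controls at 6 h, was at least 10.3-fold higher, miR-874 at least 5.53-fold higher, and at 24 h miR-1207-5p at least 5.36-fold higher. All 5 members of miR-23/24/27 were lower in the MF controls at 6 h, and so were miR-10b (−0.94), miR-26b (−0.73), miR-146a (−0.61) and miR-410 (−0.60), whose levels set the base of the MF changes at 6 h. Under normexp miR-10b, miR-26b, miR-146a and miR-410 turned to 0.35, 0.17, 0.37 and 0.28. In limma 49 miRNAs passed at 6 h, 25 that were higher and 24 lower, and 37 passed at 24 h, all higher. The scaling over all human probes gave 10 and 3 at 6 h and 4 and 109 at 24 h, and centred arrays gave 22 and 52 at 6 h and 10 and 10 at 24 h. A replicate block gave 23 and 25 miRNAs and a slide block 34 and 14. Within the slide that held both schedules, with 1 array a group, the median of the GC-rich list was 0.968 at 6 h and 0.970 at 24 h. The count at 6 h was 16, 20 and 25 without MF control 6 h replicate 2, SD control 6 h replicate 3 and SD control 6 h replicate 1, and the count at 24 h was 15 and 20 without SD control 24 h replicate 1 and MF control 24 h replicate 2. Camera called the GC-rich list higher at 6 h (2.18e-15, 0.018 with an estimated correlation) and at 24 h (4.7e-06, 0.257 with an estimated correlation). At 6 h the fragments (0.00094) were called higher and the miR-23/24/27 (0.011) and endothelial (0.048) lists lower, with adjusted p = 0.45, 0.45 and 0.63 with an estimated correlation, and the endothelial call was lost with a replicate block (0.175) or slide block (0.056). At 24 h miR-17-92 (0.00014) and let-7 (0.016) were called lower, with adjusted p = 0.26 and 0.71 with an estimated correlation. With a slide block let-7 was lost (0.153) and 14q32 was called higher (0.0062, against 0.339).

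Markers of other cell types were not detected. None of 12 markers of smooth muscle, fibroblasts and muscle, 7 of epithelium, 8 of blood cells and 13 miRNAs of the placental cluster on chromosome 19 was detected on any of the 24 arrays.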

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

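The tests of array scaling on the mostly upward calls and on the schedule difference, of the bright patch and of the doubted control arrays, and the splits that keep replicate numbers, were chosen only after the results were seen.

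The effect of irradiation at 6 h differed between the schedules by a test of the difference itself, SD minus MF, for 10 named miRNAs. miR-886-3p differed by 1.58, from effects of −0.13 in SD and −1.71 in MF. miR-923 differed by 1.20 (0.45 and −0.75), miR-1274a by 1.00 (−0.04 and −1.04), miR-7 by 0.82 (−0.12 and −0.94) and miR-18b by 0.65 (0.08 and −0.57). miR-146a differed by −1.57 (0.27 and 1.83), miR-410 by −1.01 (0.14 and 1.16), miR-377 by −0.97 (0.06 and 1.03), miR-337-5p by −0.96 (0.14 and 1.09) and miR-379 by −0.86 (0.11 and 0.98), but miR-410, miR-337-5p and miR-379 were called in 0 of 7 other scalings and miR-377 in 2. Between times, the effect of the single dose on miR-136 differed by 0.88, from 0.03 at 6 h to 0.91 at 24 h, a call lost in each of the 7 other scalings.

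The calls were mostly rises: 98.4% of them in SD at 24 h, 74.3% in MF at 6 h and 63.3% in MF at 24 h. With arrays centred on the median of tested miRNAs rises were 6.67%, 47.8% and 45.9% of the calls, but centring itself evens the balance, so these shares decide nothing about scaling as the cause. Without any scaling the median change was −0.034 in SD at 24 h, which goes with dimmer irradiated arrays being scaled up, but 1.31 in MF at 6 h and 0.44 in MF at 24 h, above the scaled medians of 0.34 and 0.18, so that scaling lowered the shift in MF. Without the 2 arrays with bright patches the median in SD at 24 h stayed at 0.348, which argues against the patches as the whole cause. A real rise of most miRNAs and a difference in array brightness both stay open, since no spike-in of known amount was used to fix the scale.

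The effects at 6 h were smaller after the single dose than after fractions. Leaving out the 2 arrays with bright patches or the 2 control arrays with the fewest detected miRNAs kept 25 and 20 of the 34 calls, but leaving out 1 of them alone, MF control 6 h replicate 2, kept 13, as few as without an array that was not doubted (SD control 6 h replicate 3, also 13), so whether those arrays made the difference stays open. With centred arrays 20% of the calls were negative, but centring moves the median difference to about 0 by construction, so whether scaling set the negative balance stays open. For miR-146a the difference held under each of 5 scalings over detected signals, with a highest adjusted p of 0.00839 (log2 −1.25 to −1.60), which argues against scaling as its cause, although it was not called under normexp (−0.14) or scaled over all human probes (−2.06). The seeding density and the dose per fraction differ between the schedules and stay open as untested explanations, and so does the time since the first fraction, which the comparison of slopes among the other observations did not decide.

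Members of the 14q32 cluster rose in SD at 24 h (22 of 35) and in MF at 6 h (23) and 24 h (7), and many members are dim, but as a list against other miRNAs it was not called in MF at 24 h, and the calls in SD at 24 h and MF at 6 h were lost with an estimated correlation (adjusted p = 0.31 and 0.335). Its median of 0.65 in SD at 24 h lay above 99.7% of random lists of other miRNAs of like signal (median 0.43), its 0.77 in MF at 6 h above 100% (0.32), and its 0.31 in MF at 24 h above 98.4% (0.19). The random lists hold miRNAs that need not move together, unlike members of 1 cluster, so these shares can overstate how far the cluster stands apart. A rise that all dim miRNAs share is therefore not excluded. A shared rise of the transcripts of this imprinted locus stays open as a hypothesis, and so does the scaling, since the median in MF at 6 h turned to −0.54 with normexp.

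Other splits of the same arrays were counted for each comparison. For the single comparisons 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 1 and 0 in SD at 6 h, 62 and 0 in SD at 24 h, 105 and 0 in MF at 6 h, 49 and 8 in MF at 24 h, 49 and 11 in controls at 6 h, and 37 and 1 in controls at 24 h. For the average 1 of 100 splits gave as many (126, highest other 58), and 1 of 100 when labels were exchanged within replicate numbers alone (highest other 84), so chance can be excluded at that level. For SD minus MF at 6 h 2 of 100 splits made without regard to replicate number gave as many (34, highest other 35). These splits break the pairs of irradiated and control arrays of a number, so they do not exclude chance. When the irradiated and control array of a number moved together, the highest other count was 0, in 10 splits, too few for a share under 0.05. For SD between times 3 of 100 splits gave as many (1, highest other 1), but so did 3 of 32 when labels were exchanged within replicate numbers (highest other 15), so chance cannot be excluded for that call. For SD minus MF at 24 h and MF between times the real count was 0, which each of the 100 of 100 splits matches by construction, so the splits say nothing about chance there. The highest other counts there, 53 and 22, lie well above 0. For SD minus MF at 24 h such splits do not cancel the difference between the schedules themselves, which gave 37 calls in controls at 24 h. These highest counts were 0 in the 10 and 4 splits that moved the irradiated and control array of a number together. For MF between times the highest was 21 when arrays were exchanged within a number alone (32 splits), and its cause was not tested.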

How the results depend on the processing

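Chosen only after results were seen were the median over spots, centring, scaling without fragments and GC-rich miRNAs, and leaving out the 2 arrays with bright patches or the 2 control arrays with the fewest detected miRNAs. Array scaling limited the calls: 33 of the 49 MF calls at 24 h and 64 of 105 at 6 h were called in the same direction under at least 5 of 7 other scalings, but 2 of 62 in SD at 24 h (miR-136 and miR-7), 8 of 34 in SD minus MF at 6 h and 0 of 1 in SD between times. Signal over background limits the dim miRNAs, since 101 of the 200 tested were detected on all 24 arrays. Over settings, 11097 values of named miRNAs kept their call with its direction, or were called neither under the main setting nor under the other. Direction was not compared for values called under neither. Of the rest, 824 kept direction and fell short of the threshold, 298 kept direction and newly passed, and 83 reversed. Of 94 list values under camera with an estimated correlation or fry, 33 kept their side and 61 fell short. The replicate block and the slide block reversed no named miRNA, but outside the contrasts of controls they could not. Each group of a schedule held the same replicates and slides, so there the blocks move only SE and p, not the log2 values. Besides the counts here the blocks changed no list call that the comparisons do not give. Leaving out each array in turn gave counts of 0 to 2 in SD at 6 h, 20 to 80 in SD at 24 h, 79 to 112 in MF at 6 h, 36 to 57 in MF at 24 h and 115 to 133 in the average. For SD minus MF these counts were 13 to 49 at 6 h and 0 to 11 at 24 h, between times 0 to 3 in SD and 0 to 3 in MF, and in controls 16 to 67 at 6 h and 15 to 44 at 24 h.

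Counts that moved by over 1.5 times, or on and off 0, were these. The median over detected probes gave 0 in SD at 6 h, 15 in SD at 24 h, 9 in SD minus MF at 24 h, 0 in SD between times and 17 in controls at 24 h. Normexp gave 0 in SD at 6 h, 1 in SD at 24 h, 23 in MF at 24 h, 31 in the average, 7 in SD minus MF at 6 h, 0 in SD between times, 20 in controls at 6 h and 9 in controls at 24 h. With miRNAs detected on all arrays, where 101 miRNAs were tested, the counts were 0 in SD at 6 h, 36 in SD at 24 h, 65 in MF at 6 h, 66 in the average, 13 in SD minus MF at 24 h, 4 in SD between times and 15 in controls at 24 h. The brightest probe gave 2 in SD at 6 h, 1 in SD minus MF at 24 h and 2 in SD between times. The total gene signal gave 0 in SD at 6 h, 79 in MF at 24 h, 9 in SD minus MF at 24 h, 0 in SD between times and 5 in MF between times. A floor of 8 gave 0 in SD at 6 h. The authors' value table gave 0 in SD at 6 h, 1 in SD at 24 h, 28 in MF at 24 h, 69 in the average, 8 in SD minus MF at 6 h, 0 in SD between times, 96 in controls at 6 h and 4 in controls at 24 h. Fitting the compared arrays alone, which leaves fewer arrays for the spread, gave 3 in SD at 6 h, 54 in MF at 6 h, 16 in SD minus MF at 6 h, 0 in SD between times, 10 in controls at 6 h and 7 in controls at 24 h. A replicate block gave 0 in SD at 6 h, 73 in SD minus MF at 6 h, 18 in SD minus MF at 24 h, 9 in SD between times, 1 in MF between times and 23 in controls at 6 h. A slide block gave 0 in SD at 6 h, 53 in SD minus MF at 6 h, 13 in SD minus MF at 24 h, 2 in SD between times and 14 in controls at 24 h. Trend and robust gave 0 in SD at 6 h and 9 in SD minus MF at 24 h. Array weights gave 2 in SD at 6 h, 107 in SD at 24 h, 26 in SD minus MF at 24 h, 9 in SD between times, 2 in MF between times and 14 in controls at 6 h. The median over spots gave 3 in SD at 6 h, 10 in SD minus MF at 24 h and 2 in SD between times. Centred arrays gave 2 in SD at 6 h, 15 in SD at 24 h, 69 in MF at 6 h, 79 in the average, 20 in SD minus MF at 6 h, 1 in SD minus MF at 24 h, 0 in SD between times, 74 in controls at 6 h and 20 in controls at 24 h. Scaling without fragments and GC-rich miRNAs gave 0 in SD at 6 h, 23 in SD at 24 h and 16 in SD minus MF at 24 h. Without the 2 arrays with bright patches there were 5 in SD at 6 h, 27 in SD at 24 h, 0 in SD between times and 15 in controls at 24 h. Without the 2 control arrays with the fewest detected miRNAs there were 0 in SD at 6 h, 22 in SD minus MF at 6 h, 10 in SD minus MF at 24 h, 2 in SD between times and 19 in controls at 6 h. The 75th percentile over all human probes gave 0 in SD at 24 h, 22 in MF at 6 h, 1 in MF at 24 h, 25 in the average, 0 in SD minus MF at 6 h, 0 in SD between times, 13 in controls at 6 h and 113 in controls at 24 h. Quantile normalization gave 7 in SD at 24 h, 3 in SD minus MF at 24 h, 0 in SD between times, 4 in MF between times, 84 in controls at 6 h and 13 in controls at 24 h. Testing all human miRNAs gave 30 in SD at 24 h, 13 in SD minus MF at 6 h, 3 in SD minus MF at 24 h, 0 in SD between times, 31 in controls at 6 h and 23 in controls at 24 h. Except where fewer arrays or miRNAs entered the fit, the cause was not tested.

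Log2 values that reversed, among those called under the main setting or the other, were these. With normexp they were miR-1181 −0.24 in SD at 6 h and miR-152 −0.037 in MF at 24 h. In MF at 6 h they were miR-216a −0.59, miR-146a −0.054, miR-369-5p −0.69, miR-487a −0.74, miR-409-5p −0.62, miR-410 −0.077, miR-136* −0.59, miR-382 −0.62, miR-337-5p −0.14, miR-495 −0.38, miR-34b* −0.59, miR-195 −0.12, miR-497 −0.52, miR-503 −0.52, miR-10b −0.59, miR-181a −0.10, miR-29b-1* −0.67, miR-181b −0.30, miR-299-5p −0.25, miR-487b −0.24 and miR-210 −0.61. In the average they were miR-572 −0.18, miR-1181 −0.13, miR-217 −0.25, miR-485-3p −0.11, miR-134 −0.15, miR-369-5p −0.22, miR-22* −0.18, miR-186 −0.24 and miR-34b* −0.091. In SD minus MF at 6 h miR-379 was 0.029, and in controls at 6 h miR-217 was 0.51, miR-10b 0.35, miR-26b 0.17, miR-146a 0.37 and miR-410 0.28. Normexp adds an offset of 50 before scaling, and a larger scale factor then lifts dim miRNAs more. Without the offset the scale factor averaged 2.05 in MF control 6 h, but the factors under normexp were not recorded. Whether the offset caused these reversals was therefore not tested. With the authors' value table the reversed values were miR-34b* −0.20, miR-874 −0.24 and miR-503 −0.33 in SD at 24 h, miR-216a −1.28, miR-369-5p −0.81, miR-487a −1.56, miR-382 −2.15, miR-34b* −0.57, miR-503 −1.08 and miR-299-5p −0.11 in MF at 6 h, miR-217 −0.030, miR-369-5p −0.11, miR-22* −0.17 and miR-34b* −0.29 in the average, miR-337-5p 0.11 in SD minus MF at 6 h, and miR-217 0.92 in controls at 6 h. With the 75th percentile over all human probes they were, in SD at 24 h, miR-34a −0.054, miR-503 −0.15, miR-27a −0.57, miR-222 −0.38, miR-31 −0.50, miR-125a-5p −0.54, miR-146a −0.24, miR-21 −0.57, miR-21* −0.46, miR-181a −0.53, miR-29a −0.60, miR-29b −0.55, miR-24 −0.61, miR-136 −0.017, miR-409-3p −0.16, miR-654-3p −0.13 and miR-127-3p −0.17, and in MF at 24 h miR-15a 0.044, miR-16 0.0011 and miR-155 0.14. With centred arrays they were, in SD at 24 h, miR-27a −0.071, miR-31 −0.0043, miR-125a-5p −0.041, miR-21 −0.071, miR-181a −0.036, miR-29a −0.11, miR-29b −0.057 and miR-24 −0.11, and with quantile normalization miR-21 −0.047 in SD at 24 h. The cause of these reversals was not tested.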

Other observations

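The test of the miR-15/16 family was chosen only after its result was seen.

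Members of the miR-15/16 family share a seed, but come from several genomic loci. At 24 h after the last fraction miR-15a (−0.48), miR-15b (−0.65) and miR-16 (−0.52) fell, miR-424 rose (0.64), and miR-195 (0.19), miR-497 (0.29) and miR-503 (0.17) did not pass. With miR-15a, miR-15b and miR-16 as 1 group, miR-195 with miR-497 and miR-424 with miR-503, 3 of 105 partitions into groups of these sizes had as small a spread within groups (share 0.0286). The groups were drawn after these values were seen, and miR-15a and miR-15b lie at separate loci, so the share does not decide between locus and mature sequence.

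Neighbouring miRNAs changed alike beyond the 14q32 and miR-17-92 clusters. Over 20 pairs of genomic neighbours the mean absolute difference of the average effects was 0.246, against 0.390 for random pairs, and a share of 0.0092 of random pairings had as small a value. Examples of average log2 changes are miR-503 (0.45) and miR-424 (0.37), and miR-195 (0.27) and miR-497 (0.33). miR-20b (−0.40) and miR-18b (−0.41) also changed alike, but they are no clear example beyond miR-17-92. Their cluster is related to it, miR-20a (−0.45) and miR-18a (−0.38) of miR-17-92 fell too, and miR-363 of their own cluster was detected on 0 arrays. Of the 20 pairs 17 had the same sign, but most average effects were positive, so many random pairs share a sign. The smaller difference between neighbours goes with shared primary transcripts, which were not measured.

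Strands of the same precursor moved together. Over 26 pairs the average effects had r 0.58 and rho 0.37, and a share of 0.0013 of random pairings had as high a correlation. In 23 pairs the sign was the same, but most average effects were positive (median 0.27), so many random pairs share a sign. In 0 pairs were the strands called in opposite directions. Within single comparisons some strands parted, in MF at 6 h miR-21 (0.80) from miR-21* (−0.32) and miR-181a (0.81) from miR-181a* (−0.16). Others there moved alike, such as miR-17 (−0.63) and miR-17* (−0.79). The correlation runs across miRNAs, which are not independent replicates, and it is consistent with changes made before the strands part.

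Whether the MF effects at 6 h resembled the SD effects at 24 h more than those at 6 h was tested, since the fractionated course had started well before its 6 h harvest. The slope on the MF effects at 6 h over 101 miRNAs was 0.184 for SD at 24 h and 0.042 for SD at 6 h, a difference of 0.142 that was at least 0.0915 with each array left out. Pearson's r with MF at 6 h was also higher for SD at 24 h, 0.393 against 0.213, but the rank correlations were nearly equal, 0.361 and 0.360, and the reverse slopes of 0.841 and 1.08 ran the other way. These measures disagree, so whether SD at 24 h resembled it more, and time since the first dose as the reason, stay open.

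Of the called miRNAs with at least 2 detected probes, 37 in SD at 24 h, 74 in MF at 6 h and 34 in MF at 24 h, 0 had probes that changed in opposite directions. The 2 control arrays with bright patches had 12.6% (MF control 6 h replicate 1) and 13.7% (SD control 24 h replicate 1) of their spots removed. The fewest miRNAs were detected on SD control 6 h replicate 4 (122) and MF control 6 h replicate 2 (123).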
